A study of Mus musculus and Gallus gallus with 7 samples.

How the data were processed

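Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to testes of C57BL/6J mice and Brown Leghorn roosters. The series holds 7 libraries. In mouse these were ChIPs of the transcription factor A-MYB, of histone H3 trimethylated at lysine 4 (H3K4me3) and of RNA polymerase II, and a control. In rooster they were ChIPs of A-MYB and H3K4me3, and a control. The controls are titled input DNA but carry an immunoglobulin G label, so their kind is unsettled. Per the labels' protocols, tissue was fixed with 1.5% formaldehyde for 20 min, chromatin was sheared by sonication, and libraries were sequenced as 50 nt reads. The same A-MYB and H3K4me3 antibodies are listed for both species.

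Processed peak lists of 4 libraries were used, namely A-MYB and H3K4me3 in each species. The polymerase II library and both controls were not analysed here. Each list belongs to 1 library and holds a chromosome, a start, an end, a peak name and a score as deposited. Peak names begin with MACS, and Bowtie 0.12.7 and MACS 1.4.1 are named per the submitters' processing notes. The caller's settings and the control it used are not given in the sources used here. The deposited score was read as −10 log10 of the caller's p-value, which is how this caller usually writes it, although no header states so. The lowest deposited score was 40, which on that reading is a p of 0.0001. Scores pile up at exactly 3100 and few lie above it, so they hardly rank the strongest peaks. The scores are the authors' own and depend on depth. They were used to describe, rank or filter the peaks of each list. The same score limits were applied to all lists, although a given score need not mean the same strength in different libraries.

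Mouse coordinates are on build mm9, per the submitters' processing notes. The same notes repeat mm9 for rooster, which does not suit rooster chromosomes, so the chicken build is not given in the sources used here. Coordinates are printed 1-based. The gene table at hand was of GRCm38.p6, a different mouse build, and no chicken annotation was used. Peaks were therefore not assigned to genes. Of the 16 results designed before the data were examined, the 7 that needed promoters or motifs were not computed, and the 12 gene lists fixed for them were not used. Regions stand in place of genes, by the rule fixed for that case. In each species it takes the 10 highest scoring A-MYB peaks (ties broken by width), the 5 highest scoring that overlap no H3K4me3 peak, and the 5 widest H3K4me3 peaks. Unplaced contigs are left out of these.

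An overlap meant at least 1 shared bp. Percentages of peaks carry 95% Wilson intervals, and differences of percentages carry 95% Newcombe intervals. Ratios of medians carry intervals from 1000 bootstrap draws of peaks. All these intervals cover counting error only. With 1 library per group there was no replicate check, and no p-value was computed, since peaks are not replicates. Read totals were not used here, so the sequencing depth behind each list is unknown. As a reference for placement, A-MYB peaks were moved along their own chromosomes by 1000 random circular shifts, and likewise H3K4me3 peaks for the reverse comparison. Chromosome extents were taken as the furthest peak end in either list of the species. The shifts do not model mappability or gene density. Strong peaks were those scoring 500 or more. That limit was chosen after seeing the data at several limits, from 40 to 1000, and after seeing the data were also chosen the comparison of strong peaks between sex chromosomes and autosomes, the position within H3K4me3 peaks, the chromosome size classes and the distance to chromosome ends.

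Alternatives fixed before the data were examined were a score of 100 or more in both lists, unplaced contigs left out, an overlap of at least 50% of the peak's length, the peak's centre inside the other peak, and the 2000 highest scoring peaks of each list. The functions were tested on simulated data. In each species, 10000 simulated peaks with the real widths were planted with 20% or 60% centred in H3K4me3 peaks, and the overlap function returned 20% and 60%. The other simulated peaks were redrawn until the same function found no overlap. These returns therefore show only that centred peaks were found, and they do not test partial overlaps. For a part of the simulated peaks, a direct comparison with every H3K4me3 peak of the chromosome gave the same count. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.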

Results

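A-MYB (MYBL1) is a transcription factor of male germ cells, and H3K4me3 is a histone mark found mainly at active promoters. Genomic sites of both were mapped in mouse and rooster testes, with 1 library per antibody and species. The mouse A-MYB list held 88032 peaks and the mouse H3K4me3 list 39997. The rooster lists held 30089 A-MYB and 31058 H3K4me3 peaks. A-MYB peaks were narrow, with a median width of 266 bp in mouse and 620 bp in rooster. H3K4me3 peaks were broader, at 1581 bp and 1434 bp. A-MYB peaks covered 25.8 Mb in mouse and 22.5 Mb in rooster, and H3K4me3 peaks covered 85.6 Mb and 55.3 Mb. Most A-MYB peaks were weak. Peaks scoring under 100 made up 82.3% of the mouse list and 63.9% of the rooster list, against 26.1% and 15.4% of the H3K4me3 lists. Strong A-MYB peaks, scoring 500 or more, numbered 1991 in mouse and 2479 in rooster.

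The first comparison asked how far A-MYB sites coincided with H3K4me3 in each testis. In mouse, 21.6% of A-MYB peaks (18975 peaks; 95% interval 21.3 to 21.8%) overlapped an H3K4me3 peak. In rooster the share was 56.7% (17060 peaks; 56.1 to 57.3%). Random shifts of the A-MYB peaks along their chromosomes gave a mean of 3.83% in mouse (range 3.56 to 4.21%) and 8.15% in rooster (7.48 to 9.42%). The observed overlap was thus 5.62 times the shifted mean in mouse and 6.95 times in rooster. For scores of 100 or more it was 12.6 and 10.3 times, and for strong peaks 20.0 (19.99) and 10.4 times. A share near 100% bounds the multiple by the shifted mean, which was higher in rooster, so the multiples do not order the species. Of the strong peaks, 89.3% in mouse (87.9 to 90.6%) and 98.2% in rooster (97.6 to 98.6%) overlapped H3K4me3. With peaks scoring 100 or more in both lists, the shares were 48.3% in mouse and 90.8% in rooster.

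The rise with score had a different shape in each species, although a given score need not mean the same strength in both libraries. In mouse the share stayed between 12.7% and 18.3% for all score classes under 100, reached 63.2% for scores of 150 to 200, and was 92.0% for scores of 300 to 500. In rooster it climbed step by step from 25.3% in the lowest class to 98.8% for scores of 500 to 1000. In both species the class of 1000 or more lay slightly lower, at 87.1% in mouse (84.7 to 89.1%) and 96.9% in rooster (95.4 to 97.9%). Within the A-MYB lists, marked peaks had a median score of 83.7 in mouse against 65.4 for unmarked ones, a ratio of 1.28 (1.27 to 1.29). In rooster the medians were 132 (131.9) and 51.1, a ratio of 2.58 (2.53 to 2.65). Among strong peaks the order was the opposite, with medians of 909.8 marked and 1094 unmarked in mouse, and 789 marked and 1050 (1049.6) unmarked in rooster. No intervals were computed for these medians. The unmarked ones rest on 213 peaks in mouse and 45 in rooster, of which 19 were on unplaced contigs. With the 2000 highest scoring peaks of each list the ratios were 0.912 (0.828 to 1.04) and 0.959 (0.885 to 1.02), but that setting took only part of the H3K4me3 peaks tied at 3100. With all tied peaks kept they were 1.10 (1.03 to 1.17) in mouse and 0.999 (0.889 to 1.11) in rooster.

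**Figure D1:**
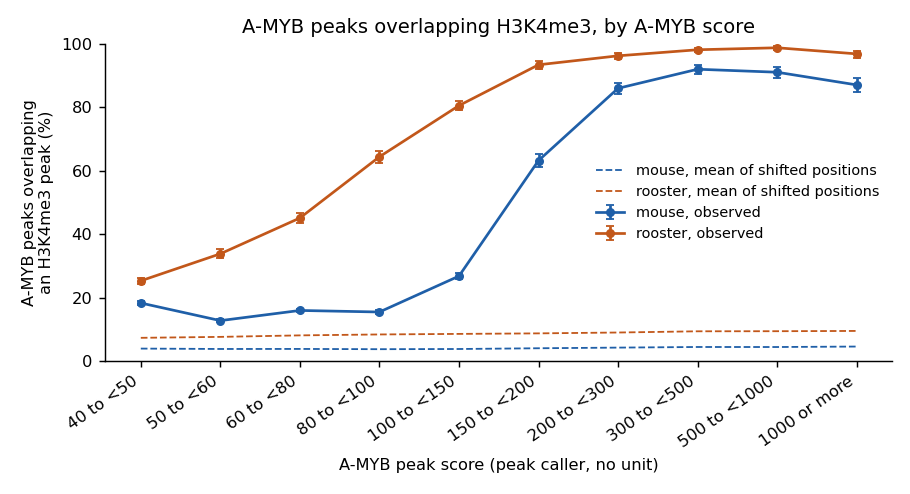
Percent of A-MYB peaks overlapping an H3K4me3 peak (y axis) by A-MYB peak score class (x axis, caller's score without unit) in mouse (blue) and rooster (orange). Points carry 95% Wilson intervals and dashed lines give the mean of 1000 circular shifts. The mouse share stays at or under 18.3% below a score of 100 and the rooster share rises from 25.3% upward.

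Seen from the H3K4me3 side, 36.2% of mouse H3K4me3 peaks (35.7 to 36.7%) and 48.5% of rooster H3K4me3 peaks (48.0 to 49.1%) carried an A-MYB peak. Shifted H3K4me3 peaks gave 7.72% in mouse and 7.33% in rooster. The share of H3K4me3 peaks with A-MYB rose with the H3K4me3 score. Among H3K4me3 peaks scoring 3100 or more, where scores pile up, 81.8% in mouse (80.8 to 82.7%) and 84.4% in rooster (83.8 to 85.1%) held an A-MYB peak. Among those scoring under 100 the shares were 11.7% and 17.9%. H3K4me3 peaks of that class were also narrower, and those without A-MYB had medians of 806 bp in mouse and 833 bp in rooster. The shifts were not split by H3K4me3 score, so the share expected from width alone is unknown. A strong A-MYB peak was present at 18.8% of H3K4me3 peaks scoring 3100 or more in mouse and 19.3% in rooster. H3K4me3 peaks with A-MYB were wider, with a median of 2590 bp against 1218 bp in mouse and 1970 bp against 1108 bp in rooster. Within a score class the widths lay much closer. At 3100 or more they were 4157 bp with A-MYB and 4234 bp without in mouse, and 2397 bp and 2333 bp in rooster. Requiring scores of 100 or more in both lists lowered the shares to 23.3% in mouse and 36.2% in rooster. Requiring 50% of the H3K4me3 peak's length gave 1.06% and 23.1%. Requiring the H3K4me3 centre to lie inside an A-MYB peak gave 13.8% in mouse and 35.4% in rooster. Both settings depend on peak widths. A-MYB peaks had medians of 266 bp in mouse and 620 bp in rooster, against 1581 bp and 1434 bp for H3K4me3. These settings therefore say little about how often the 2 kinds of peak meet.

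A-MYB peaks tended to sit in the middle of H3K4me3 peaks. Of the strong A-MYB peaks with their centre inside an H3K4me3 peak, 68.7% in mouse (66.5 to 70.8%; 1772 peaks) and 70.7% in rooster (68.9 to 72.5%; 2433 peaks) lay in the central 33.3% of its width, where an even spread would place 33.3%. Over A-MYB peaks of any score the shares were 54.2% and 58.3%. Of the H3K4me3 peaks that contained an A-MYB centre, 3414 of 14207 in mouse (24.0%; 23.3 to 24.7%) and 1639 of 14967 in rooster (10.5 to 11.5%) contained 2 or more, with up to 7 in mouse and 6 in rooster. With strong A-MYB peaks alone, 1.84% and 0.537% did.

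The second comparison set mouse beside rooster. The share of A-MYB peaks with H3K4me3 was lower in mouse, with a mouse minus rooster difference of −35.1 percentage points (−35.8 to −34.5). Among strong A-MYB peaks the difference was −8.88 points (−10.4 to −7.46), and among the 2000 highest scoring A-MYB peaks of each species −8.70 points (−10.2 to −7.24). With scores of 100 or more in both lists it was −42.5 points. With the 2000 highest scoring peaks of each list it turned to 8.35 points (6.08 to 10.6), a setting that took only part of the H3K4me3 peaks tied at 3100, and it was −32.2 points with all tied peaks kept, an alternative chosen after seeing the data. Species, build, depth, and number and width of peaks differ together between these lists and cannot be separated. Antibody fit may differ too. Rooster A-MYB peaks were wider (median 620 bp against 266 bp). Rooster H3K4me3 peaks also covered more of the chromosome extent, at 5.05% against 3.24%. The overlap after random shifts was accordingly higher in rooster, at 8.15% against 3.83%.

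The sex chromosomes were compared with the autosomes. Male mice carry a single X, which is silenced as a whole in meiotic prophase, whereas roosters carry a pair of Z chromosomes. The mouse X held 1.94% of A-MYB peaks (1706 peaks; 1.85 to 2.03%) and 2.87% of H3K4me3 peaks (2.71 to 3.04%), with 6.31% of the chromosome extent. Its A-MYB density of 10.2 peaks per Mb lay below that of all 19 autosomes (29.8 to 44.8). Its H3K4me3 density of 6.88 per Mb also lay below all of them (12.7 to 21.5). A single copy could lower the scores of both lists on X, and its effect on A-MYB peaks was not tested. Among peaks scoring 500 or more the order was the other way round: X held 3.97% of A-MYB peaks (79 peaks; 3.20 to 4.92%) and 2.55% of H3K4me3 peaks (2.33 to 2.80%). X had 17.9 strong A-MYB peaks per 100 strong H3K4me3 peaks, above each of the 19 autosomes (8.94 to 13.4). Of the 79 strong A-MYB peaks on X counted here, 33 overlapped no H3K4me3 peak. Per Mb, strong A-MYB peaks on X (0.474) stayed below the lowest autosome, chromosome 3 (0.552). The rooster Z held 5.09% of A-MYB peaks (4.85 to 5.35%) and 5.90% of H3K4me3 peaks (5.64 to 6.16%). Among strong peaks these were 3.91% (3.22 to 4.75%) and 5.63% (5.31 to 5.97%). Z had 9.05 strong A-MYB peaks per 100 strong H3K4me3 peaks, below the autosomal median of 13.7 and above 1 of the 27 autosomes that had a strong A-MYB peak (7.55 to 18.2).

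Strong A-MYB peaks on the mouse X often lacked H3K4me3. On X, 46 of 79 strong A-MYB peaks overlapped H3K4me3 (58.2%; 47.2 to 68.5%), against 1732 of 1908 on autosomes (90.8%; 89.4 to 92.0%). The difference was −32.5 percentage points (−43.6 to −22.2). The lowest autosomal share was 85.2%, on chromosome 3. The 33 unmarked strong peaks on X outnumbered those of any autosome, the next being chromosome 1 with 18. Of these 33, 23 lay more than 10 kb from the nearest H3K4me3 peak. The median distance over the 33 was 31.0 kb. On autosomes, 135 of 176 unmarked strong peaks lay more than 10 kb away, with a median distance of 41.0 kb. Over X peaks of any score the share with H3K4me3 was 22.5%, against 21.5% on autosomes (difference 0.967 points; −0.971 to 3.03). At scores of 100 or more it was 44.0% against 50.3% (difference −6.24 points; −11.0 to −1.33). On the rooster Z, 95 of 97 strong A-MYB peaks were marked (97.9%; 92.8 to 99.4%), against 98.9% on autosomes (difference −0.993 points; −6.15 to 0.588). At scores of 1000 or more the Z share was 91.3% of 23 peaks, against 98.1% on autosomes (difference −6.75 points; −24.9 to −0.345). The mouse Y had 4 strong A-MYB peaks, of which 0 overlapped H3K4me3, too few to set a share.

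**Figure D2:**
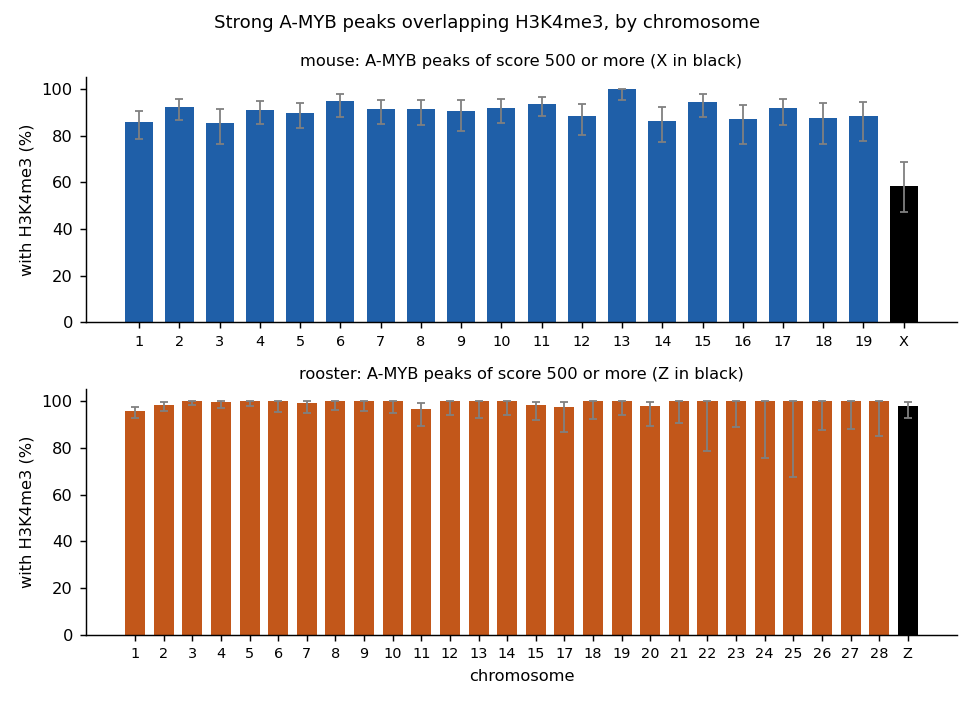
Percent of A-MYB peaks scoring 500 or more that overlap an H3K4me3 peak (y axis) on each chromosome (x axis) of mouse (top) and rooster (bottom), with 95% Wilson intervals; chromosomes with under 8 such peaks are not drawn. The mouse X (black) stands at 58.2% and the mouse autosomes at 85.2% or more, while the rooster Z (black) stands at 97.9%.

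Across rooster chromosomes the density of both peak kinds followed chromosome size. The large chromosomes 1 to 5 had 20.4 A-MYB and 21.5 H3K4me3 peaks per Mb, chromosomes 6 to 10 had 31.9 and 26.6, and chromosomes 11 to 28, which are mostly the gene-dense microchromosomes, had 49.9 and 44.0. Strong A-MYB peaks had densities of 1.80, 2.88 and 3.82 per Mb in these classes. The share of H3K4me3 peaks with A-MYB was 48.4% (47.5 to 49.2%), 56.7% (55.2 to 58.2%) and 55.0% (53.9 to 56.1%). In mouse, autosomal A-MYB density ranged from 29.8 per Mb on chromosome 3 to 44.8 on chromosome 11, and H3K4me3 density was also lowest and highest on these chromosomes, at 12.7 and 21.5. The share of H3K4me3 peaks with A-MYB was lower on the sex chromosome than on each of the autosomes compared, at 26.9% on X (mouse autosomes 30.8 to 42.5%) and 40.3% on Z (rooster autosomes 41.3 to 63.4%). No intervals were computed for these shares. The margin on Z was narrow, and the lowest rooster autosome, chromosome 25, had only 155 H3K4me3 peaks.

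**Figure D3:**
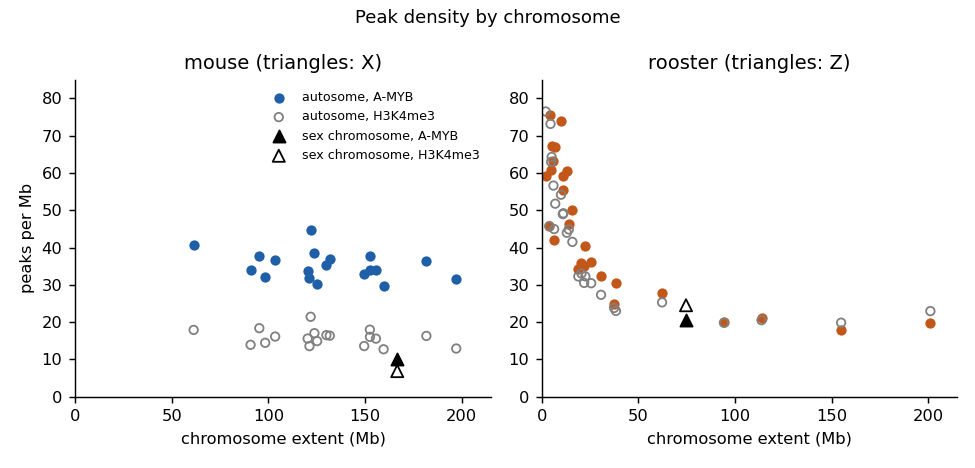
Peaks per Mb (y axis) against chromosome extent in Mb (x axis) for A-MYB (filled) and H3K4me3 (open) in mouse (left) and rooster (right), 1 point per chromosome and list; the mouse Y and rooster chromosome 16 are not drawn. Rooster densities fall from 75.6 A-MYB peaks per Mb on chromosome 28 to 17.9 on chromosome 2, and the mouse X (triangles) lies at 10.2.

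Of the 10 highest scoring mouse A-MYB peaks, 7 lay within H3K4me3 peaks, and 5 of those H3K4me3 peaks scored 3100. The top peak spanned chromosome 9 from 43892407 to 43893307 (mm9; 901 bp; score 3225) inside an H3K4me3 peak of 6775 bp. The others with H3K4me3 started at 50560042 on chromosome 13 (score 3210), 137748374 on chromosome 5 (3181), 107854830 on chromosome 11 (3180), 136858662 on chromosome 1 (3171), 125141324 on chromosome 6 (3165) and 55083852 on chromosome 1 (3161). The remaining 3 had no H3K4me3, and 2 of these were on X. They spanned X from 21327615 to 21328075 (score 3218; 4.75 kb from the nearest H3K4me3 peak), chromosome 7 from 147550004 to 147550565 (3198; 128.3 kb away) and X from 166428729 to 166429931 (3151; 63.0 kb away). The next strongest unmarked peaks were on chromosome 5 from 71584716 to 71585349 (3103) and on chromosome 17 from 39979796 to 39985915 (3100). The last was the widest A-MYB peak of the list at 6120 bp. Genes and repeated sequence at these positions were not determined.

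In rooster, 9 of the 10 highest scoring A-MYB peaks lay within H3K4me3 peaks, all of these scoring 3100. Of the 10 A-MYB peaks, 3 scored above 3100. The others were the widest of those tied at 3100, so they were picked by width. The top peak spanned chromosome 7 from 27776332 to 27777541 (score 3152; 1210 bp), and another spanned chromosome 5 from 12600103 to 12601205 (3107). The other 7 marked peaks lay within 50 kb of the far end of their chromosome's extent. They started at 10899143 and 10894967 on chromosome 18, 9927440 on chromosome 19, 6036093 on chromosome 23, 18871124 on chromosome 13, 30650677 on chromosome 8 and 38356730 on chromosome 7, with widths of 1915, 3508, 4081, 3369, 2984, 2941 and 2734 bp. The unmarked one spanned chromosome 1 from 104457135 to 104461609 (4475 bp; score 3100). Of the 5 highest scoring unmarked rooster peaks, 4 lay on chromosome 1 between 104451330 and 104485048, and the other was on chromosome 7 from 7304125 to 7306217 (2849).

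The widest mouse H3K4me3 peak spanned chromosome 2 from 92209295 to 92233369 (24075 bp) and held 1 A-MYB peak of score 54.8. The next, on chromosome 16 from 10780231 to 10803256 (23026 bp), held 3 with a top score of 1069, and that on chromosome 9 from 107441956 to 107460693 (18738 bp) held 2 with a top score of 1162. Those on chromosome 15 from 89000478 (21363 bp) and chromosome 3 from 94274027 (18660 bp) held only weak A-MYB peaks, with top scores of 75.2 and 72.5. The 5 widest rooster H3K4me3 peaks held 3 or 4 A-MYB peaks each. The top scores were 3032 in the peak on chromosome 20 from 9973999 to 9988949, 1225 on chromosome 23 from 5441090 to 5456612, 317 (316.8) on chromosome 1 from 51200640, 108 (108.1) on chromosome 26 from 5081027 and 92.9 on chromosome 20 from 1928484.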

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

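The alternatives with an A-MYB score of 500 or more or the 2000 highest scoring A-MYB peaks alone, the one that kept all tied H3K4me3 peaks, and the X and Z differences with theirs, were tests chosen only after the result was seen. Of 60 alternatives run on the results reported, 16 kept the direction inside the main result's 95% interval, 39 kept it outside that interval, and 5 reversed, of which the Z difference stayed inside its interval. The 16 include the mouse results without unplaced contigs, which could not change because the mouse lists hold 0 such peaks. With scores of 100 or more in both lists, A-MYB peaks with H3K4me3 were 48.3% in mouse and 90.8% in rooster (difference −42.5 points), H3K4me3 peaks with A-MYB 23.3% and 36.2%, A-MYB peaks on X 2.63% and on Z 4.49%, and the score ratio of marked to unmarked A-MYB peaks 1.87 in mouse and 2.08 in rooster. An A-MYB score of 500 or more gave 89.3% and 98.2% (difference −8.88 points), with 3.97% on X and 3.91% on Z, and the 2000 highest scoring A-MYB peaks against all H3K4me3 peaks gave 89.4% and 98.1% (89.35, 98.05; difference −8.70). Requiring 50% of the peak's length gave 21.1% and 56.0% of A-MYB peaks, and 1.06% and 23.1% of H3K4me3 peaks. Requiring the centre inside gave 21.1% and 56.0% of A-MYB peaks, and 13.8% and 35.4% of H3K4me3 peaks. For H3K4me3 peaks these 2 settings depend on peak widths, since A-MYB peaks were narrower, above all in mouse. Without unplaced contigs, rooster H3K4me3 peaks with A-MYB were 51.0%, A-MYB peaks on Z 5.47%, and the rooster score ratio 2.68; in mouse this setting removed nothing. With the 2000 highest scoring peaks of each list, A-MYB peaks with H3K4me3 fell to 20.3% in mouse and 12.0% (11.95) in rooster, H3K4me3 peaks with A-MYB to 20.0% (19.95) and 12.0% (11.95), the species difference turned to 8.35 points, and the score ratios to 0.912 and 0.959. This setting cut the H3K4me3 lists to 2000 peaks, and by file order took 1660 of 5774 mouse and 1838 of 11492 rooster H3K4me3 peaks tied at 3100. With all tied peaks kept, A-MYB peaks with H3K4me3 were 59.3% and 91.5%, the species difference returned to −32.2 points, H3K4me3 peaks with A-MYB were 18.9% and 15.6%, and the score ratios 1.10 in mouse and 0.999 (0.889 to 1.11) in rooster. The X minus autosome difference for strong A-MYB peaks stayed within its interval, at −24.1 points for scores of 200 or more, −34.7 for 1000 or more and −33.0 with H3K4me3 within 1 kb counted. At still lower limits it left that interval, at −6.24 points (−11.0 to −1.33) for scores of 100 or more and 0.967 points (−0.971 to 3.03) over all scores. These last limits are not among the 60 alternatives. The Z minus autosome difference was 0.142 points at 200 or more and −6.75 (−24.9 to −0.345) at 1000 or more, where Z had 23 peaks. The cause of the other changes was not tested. The designed results on promoters, gene lists, shared genes and motifs, with their alternatives, were not run, since no annotation or genome of the build was used. Read depth is unknown, so a missing peak is not a missing site.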

Other observations

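The tests of the rooster Z, of peak borders and of weak-peak placement, and the counts of unmarked peaks, were chosen only after the result was seen. In mouse, unmarked A-MYB peaks of any score were mostly more than 10 kb from any H3K4me3 peak (45268 of 67704 on autosomes and 1069 of 1322 on X). Strong A-MYB peaks without H3K4me3 were also mostly that far away, so the distance is not particular to them. Of 213 such strong peaks, 8 lay within 1 kb of an H3K4me3 peak, 43 at 1 to 10 kb and 162 further away. In rooster, of 45, 4 lay within 1 kb, 13 at 1 to 10 kb and 28 further away or on a sequence with no H3K4me3 peak, and 19 of the 45 were on unplaced contigs. The unmarked strong peaks of mouse were narrower than the marked ones, with a median of 480 bp against 717 bp (716.5), while their median score was 1094 against 909.8. Of the 94 unmarked rooster A-MYB peaks scoring 200 or more on placed chromosomes, 12 lay on chromosome 1 between 104451330 and 104493841, with scores of 366 (365.7) to 3100. In mouse, 516 such peaks were counted in fixed, adjoining windows of 100 kb, and stretches across a window border were not examined. No such window held more than 3, and 4 windows held 3 each. They lay on chromosome 2 from 98502319 to 98507560 and chromosome 9 from 3002026 to 3025978. The others were on chromosome 11 from 6348123 to 6355159 and X from 21312491 to 21355389. Repeated sequence at these places was not examined in either species.

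The mouse X showed strong A-MYB peaks without H3K4me3 (58.2% marked, against 90.8% on autosomes). A single X copy would halve the DNA and so lower H3K4me3 scores there, but when autosomal H3K4me3 peaks had to score 160 or more, 4 times the lowest score, 88.9% of strong autosomal A-MYB peaks (87.5 to 90.3%) were still marked, above the upper limit of 68.5% on X. Clusters of strong peaks within 100 kb were argued against as the whole account: without strong peaks that had another unmarked one within 100 kb, 65.2% of 66 X peaks (53.1 to 75.5%) were marked, against 91.8% (90.5 to 93.0%) on autosomes. The X share was 58.2% of 79 peaks before this step, so such clusters may account for part of the difference. Clusters with weaker members or wider spacing were not covered by the test. On the rooster Z 97.9% were marked, and at scores of 1000 or more 91.3% of 23, against 98.1% on autosomes (difference −6.75 points; −24.9 to −0.345), so a property of the mouse X that the Z lacks stays a hypothesis, as species, build and depth differ along with the chromosome and nothing here separates them. Scattered repeats and a read surplus in the control stay open, since neither genome sequence nor control was analysed here.

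Many of the rooster A-MYB peaks at the top of the score range lay near chromosome ends: 11 of the 22 on placed chromosomes scoring 3100 or more were within 50 kb of an end (50.0%; 30.7 to 69.3%), against 3.63% of the 744 scoring 1000 or more, 1.96% of the 2343 scoring 500 or more, 0.907% of the 28018 of any score and 1.04% of H3K4me3 peaks scoring 3100 or more. Repeated sequence that raises reads in every ChIP was tested as set beforehand, and the outcome was opposite to its prediction: of the 27 A-MYB peaks scoring 1000 or more near ends, 81.5% overlapped an H3K4me3 peak scoring 3100 or more (63.3 to 91.8%), fewer than the 95.4% of the 717 elsewhere (93.6 to 96.7%). That test decides nothing, because even 27 of 27 would have had a lower limit of 87.5%, under the upper limit of 96.7% elsewhere, so repeated sequence and binding cannot be told apart at these ends. A test of borders, added once that outcome was known, went with sequence at the ends that gives both ChIPs like peaks: 25.9% of the 27 had both borders within 100 bp of an H3K4me3 peak's borders (13.2 to 44.7%), against 2.65% elsewhere (1.70 to 4.10%). Some of those with like borders were among the 10 highest scoring peaks named above, so the test is not independent of the pattern. The end peaks were also not matched in width with the others. Sequence and control reads at the ends were not analysed here, and no biological explanation was tested.

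Weak peaks made up most of the mouse A-MYB list. Random placement of the weak peaks as a whole was argued against, since 15.4% of peaks scoring under 100 (15.2 to 15.7%) overlapped H3K4me3, above the highest of 1000 shifts at 4.15%. This speaks for a minority of them, and random placement of the rest stays open. Open chromatin that gives extra reads in any library may still account for part of them, which the control library, not analysed here, would show.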
